A study of Mus musculus with 44 samples.

How the data were processed

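RNA sequencing was done on innate lymphoid cells (ILCs) sorted from the intestine of mice, 44 libraries in all, per the labels. The values come in 2 tables that were normalised apart. The Bcl6 table holds 24 libraries in 8 groups of 3: natural killer (NK) cells, ILC1, CCR6-negative ILC3 and CCR6-positive ILC3 of the small intestine (SI) at steady state, each from 2 genotypes. Mice of the first genotype carry Bcl6 alleles that Cre can delete but no Cre, and are called WT here. Mice of the second carry the same alleles with Ncr-Cre, a Cre driven in cells that express Ncr1, and their libraries are called KO after the labels. The wild-type table holds 20 libraries in 11 groups of 1 to 3 from the SI and the large intestine (LI), where 4 LI libraries come from mice infected with the bacterium Citrobacter rodentium. Their characteristics give 4 days after infection; the titles of 3 of them give day 3.5 and the other title 4 days. Per the labels' protocols, the Bcl6 libraries were made from poly-A RNA with a strand-keeping kit and the wild-type libraries with an amplification kit.

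Per the submitters' processing notes, STAR, HTSeq, DESeq2 and the mm10 build were used, without roles, versions or settings. Both value tables hold log2-scale values deposited by the authors after the variance-stabilising transformation of DESeq2. The authors also corrected the wild-type table for batch, per the labels, by a method that is not stated; no correction is named for the Bcl6 table. The tables of differences deposited by the authors give log2 fold changes with their standard errors, p-values and adjusted p-values; the model behind them is not stated. No quality-control or read files were used, and replicates were not pooled.

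In the Bcl6 table the transformation was inverted. All values (100%) gave whole read numbers within a tolerance of 0.001 reads, with a largest distance of 6.6e-09, so the table holds uncorrected values and the reads per gene could be recovered. Recovered totals ran from 2.56 to 14.99 M reads per library, and counts per M reads (CPM) were computed from them. Where no read was found, a floor of 3 reads over the group limits the level, which covers counting error only, since reads without molecular identifiers are not independent molecules. The transformation compresses differences of weakly expressed genes, so log2 differences of the values understate the ratio of CPM there. The depth of the wild-type libraries is unknown. In that table genes without reads take 1 value per set of libraries, which showed 3 sets that had been corrected apart. Of the 57 pairs of libraries in a shared set the lowest had 9.1% of values equal, and of the 133 pairs across sets the highest had 1.2%. Where a title has a replicate number the sets follow it, with numbers 3 and 4 in the third set. The 5 libraries of the SL series have no number in the title; LI ILC2 2 fell in the second set and the other 4 in the first. Their replicate numbers in this text are assigned. NK cells and ILC1 occur in the third set alone.

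Each table was fitted as a whole with limma 3.58.1 in R 4.3.3, with 1 mean per group and a trend of the variance on the mean value (limma-trend). The wild-type fit had a term for the library series of the titles. Groups of 1 library were assumed to vary like the others. A gene was tested when its value lay over the table's floor, the 1st percentile of all values, by at least 1 in at least 3 libraries of the Bcl6 table or 2 of the wild-type table. This left 10256 of 24154 and 17364 of 21770 genes, and in the Bcl6 table the limit equals 24 to 142 reads. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and standard errors (SE) are limma's. Each of the 20 comparisons used these fits, 10 per table. Every adjusted p in the text comes from limma. The p-values measure the spread between these libraries; the labels do not say whether replicates are separate mice, pools or sorts. WT mice had no Cre, so effects of Cre and of the deletion cannot be told apart.

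The 20 gene lists, 342 genes in all, were tested with limma's camera at a preset correlation of 0.01 and, beside it, with an estimated correlation, with adjustment over the lists of a comparison. The lists are type 1 effector genes, NK-associated genes, ILC1-associated genes, ILC2-associated genes, type 3 genes, LTi-like genes (after lymphoid tissue inducer cells), the type 1 module of CCR6-negative ILC3, Bcl6-repressed genes in T and B cells, interferon response, cell cycle, immediate early and stress genes, NF-kB target genes, and tissue retention and trafficking. The markers of other cell types are epithelium, T cells, B and plasma cells, myeloid cells, stroma and endothelium, mast cells, and red blood cells. Some genes stand in several lists. Lists with fewer than 3 tested members had no test.

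Genes are named by a rule. For each comparison it takes the 10 largest rises and the 10 largest falls among called genes whose higher group has a mean at or above the median of tested genes and, for comparisons of 2 groups, whose values do not overlap. It adds up to 4 members of each list with a call or with at least 3 members past the threshold. It always includes a fixed set of regulators and receptors, among them Bcl6, Ncr1, Tbx21, Eomes, Gata3, Ahr, Prdm1 and Il7r. The text gives a selection of the genes that the rule names, and a few others as called list members or shared calls. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Coordinates come from the GENCODE vM21 annotation of GRCm38 (mm10), matched by symbol.

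The alternatives were no filter, a stricter filter of 3 over the floor, quantile normalisation, a shift of library medians, no variance trend, library weights (arrayWeights), a fit of the compared groups alone, a replicate block (in the wild-type table the number in the title, with the SL series as a level of its own), limma-voom with TMM scaling on recovered reads, other batch terms, leaving out the SL library series of the titles, and leaving out each library. Alternatives chosen after seeing the data were the correction sets as batch term, leaving out the SI libraries with Y-linked reads, leaving out the 2 NK libraries of highest stroma score, removing each library's trend on transcript length, and list scores as covariates. The transformation's inverse was tested on 20000 simulated values, all recovered.

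The limma fits were tested on simulated values with 200 changed genes and with none. Without changes, 0 genes were called in either table. In simulations of the KO comparison, changes of 2 on the log2 scale were recovered for 97% of genes in NK cells, 98% in ILC1, 99% in CCR6-negative ILC3 and 100% in CCR6-positive ILC3. Changes of 1 were recovered for 38% in NK cells, 51% in ILC1, 48% in CCR6-negative ILC3 and 46% in CCR6-positive ILC3. The simulated noise was independent between libraries and had 1 SD per gene over all groups. NK libraries of a group correlated at 0.835 to 0.878 and those of the other Bcl6 groups at 0.902 or more. The NK figures and the count of 0 therefore do not cover the wider spread of the NK libraries.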

Results

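The Bcl6 table compares 4 ILC subsets of the small intestine between mice with and without Ncr-Cre on floxed Bcl6 alleles, 3 libraries per subset and genotype. Recovered totals were 2.56 to 4.59 M reads in NK WT, up to 9.98 M in NK KO, 9.95 to 10.21 M in ILC1 WT, 3.57 to 11.11 M in ILC1 KO, 9.87 to 14.7 M in CCR6-negative WT, 11.24 to 14.69 M in CCR6-negative KO, 8.76 to 13.55 M in CCR6-positive WT and 11.08 to 14.99 M in CCR6-positive KO. The wild-type table compares 5 subsets of the SI (2 libraries each of NK cells, ILC1 and ILC2, and 3 of each ILC3 subset), 3 subsets of the LI at steady state (2 ILC2 libraries and 1 of each ILC3 subset) and the same LI subsets after infection (1 of ILC2, 1 of CCR6-positive ILC3 and 2 of CCR6-negative ILC3). Correlation between libraries of a group ran from 0.835 to 0.972 in the Bcl6 table and from 0.954 to 0.981 in the wild-type table.

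Bcl6 encodes the transcriptional repressor targeted in the KO mice (chromosome 16, 23965052 to 23988852, mm10). Its gene-level reads did not differ past the threshold in libraries labelled Bcl6 KO. NK cells held 31.6 to 82 CPM in WT and 36.2 to 107 CPM in KO, ILC1 held 21.6 to 51.1 and 14.6 to 48.6, CCR6-negative ILC3 held 13.1 to 19.8 and 23.7 to 35.3, and CCR6-positive ILC3 held 25 to 33.9 and 8.03 to 42.8. The log2 differences were 0.21 (adjusted p = 0.766), -0.12 (adjusted p = 0.952), 0.4 (adjusted p = 0.713) and -0.31 (adjusted p = 0.844). Gene-level reads include exons outside a deleted part, so they check neither the labels nor the deletion, and KO stands for the label throughout. Ncr1, the gene whose activity drives the Cre and which encodes the NKp46 receptor, was at 0.34, 0.326, 0.377 and 0.908 of the WT level in NK cells, ILC1, CCR6-negative and CCR6-positive ILC3.

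The KO label was compared with WT in each subset to find the genes that differ with it. In CCR6-negative ILC3 the cytokine genes Il17a and Il17f, whose products call neutrophils and act on epithelium, rose most. Il17f rose from 58.8 ± 8.38 to 860 ± 278 CPM (SD, n = 3; log2 difference 3.27, SE 0.23, adjusted p = 2.82e-12) and Il17a from 14.2 ± 7.53 to 272 ± 104 CPM (log2 difference 2.83, SE 0.27, adjusted p = 1.2e-08). They neighbour each other on chromosome 1 (20730905 to 20734496 for Il17a, 20777146 to 20790617 for Il17f, mm10). Also higher were Gzmb and Gzmc, 2 granzymes of one gene family whose reads can be shared (log2 differences 2.01 and 1.8), Slc16a10, an amino acid transporter (1.8), Cables1, an adaptor of cell cycle kinases (1.78), Plekhg1, a guanine nucleotide exchange factor (1.62), the nuclear pore gene Nup98 (1.56), the elongation factor gene Aff1 (1.47) and Nfkb1 (1.32). Lower were Cd160, a receptor of cytotoxic lymphocytes (-1.1), and Ncr1 (-1.19, SE 0.28, adjusted p = 0.017), whose call was lost without WT 1, WT 3, KO 2 or KO 3 at -1.28 to -0.99. Tbx21, a regulator of the type 1 lineage, did not pass (-0.32, adjusted p = 0.776).

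Of the type 3 genes, which serve the IL-17 and IL-22 programme, 5 of 19 tested members were higher in CCR6-negative KO, among them Stat3 and Rora (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.000614; adjusted p = 0.0956 with an estimated correlation). NF-kB target genes had 3 of 18 higher with a median log2 difference of 0.36 (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.00142; adjusted p = 0.367 with an estimated correlation). LTi-like genes moved up by a median of 0.29 with 2 of 19 called, Il17a and Il17f (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.00259; adjusted p = 0.367 with an estimated correlation). Genes of the immediate early and stress list, which respond within minutes to stimulation or cell isolation, lay lower by a median of -0.61, with 3 of 20 lower and Nr4a2 (1.27) higher (1 higher and 9 lower adjusted over the list alone; adjusted p = 1.48e-06; adjusted p = 0.13 with an estimated correlation). In total limma called 151 of 10256 genes, 126 higher and 25 lower. The count moved to 50 without WT 1, 40 without WT 3, 74 without KO 1, 79 without KO 2 and 67 without KO 3, and Il17a, Il17f, Gzmb, Gzmc, Slc16a10, Cables1, Plekhg1, Nup98, Aff1, Nfkb1 and Cd160 stayed called in each. Stat3 (1.16) was lost without WT 1, WT 3 or KO 3 (1.04 to 1.1), Rora (0.81) without WT 1, WT 3, KO 1 or KO 2 (0.74 to 0.8) and Nr4a2 without WT 3 (1.17). Quantile normalisation called 142 genes, 104 higher and 38 lower. Differences rose with transcript length (Spearman 0.35 across genes; median length 5000 bases for raised, 2623 for lowered and 3472 for tested genes). With the length trend of each library removed, a setting chosen after seeing the data, 107 of the 147 calls with a known length were kept. How far the differences of the other calls shrank is not given, so a part of the calls may move with length. The authors' deposited table called 299 genes, 135 of them in both and all in the same direction.

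CCR6-positive ILC3 barely express Ncr1 (23.7 ± 21.1 CPM in WT, n = 3), yet Il17a and Il17f rose in their KO libraries too. Il17f rose from 216 ± 16.9 to 1550 ± 47.7 CPM (log2 difference 2.68, SE 0.23, adjusted p = 1.04e-09) and Il17a from 53 ± 5.61 to 403 ± 77.5 CPM (2.36, SE 0.27, adjusted p = 1.39e-06). The granzyme genes Gzmb (2.26) and Gzmc (1.71), the elongation factor gene Ell2 (1.5) and the tRNA synthetase gene Eprs (1.46) were also higher. Lower were the near-identical heat shock genes Hspa1b (-2.09) and Hspa1a (-1.81), whose reads cannot be told apart with certainty, and the nuclear receptor coactivator Ncoa7 (-1.43). The immediate early gene Jun fell by 1.39, but its call was lost without WT 1, WT 2 or KO 3 (-1.4 to -1.09), and Fos fell by 1.86, lost without WT 1, WT 2, WT 3, KO 2 or KO 3 (-1.91 to -1.5).

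The stress list again lay lower in CCR6-positive KO by a median of -0.84, with 6 of 20 lower (1 higher and 11 lower adjusted over the list alone; adjusted p = 4.79e-14; adjusted p = 0.0168 with an estimated correlation). Type 3 genes lay higher with 4 of 19 called, Il17a, Il17f, Stat3 and Rora (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.000486; adjusted p = 0.0585 with an estimated correlation). Of these Stat3 was lost without WT 1 (1.13) or KO 3 (1.03) and Rora when any 1 of the 6 libraries was left out (0.67 to 0.76). Il2rb (1.08) was lost without WT 1 (0.86) or KO 3 (0.96), and Nfkb1 (1.18) without KO 3 (1.02). Type 1 effector genes, the cytotoxic and interferon programme, had 3 of 20 higher, Gzmb, Gzmc and the IL-2 and IL-15 receptor chain Il2rb (3 higher and 0 lower adjusted over the list alone; adjusted p = 0.000329; adjusted p = 0.244 with an estimated correlation). NF-kB target genes had a median of 0.36 with Nfkb1 called (4 higher adjusted over the list alone; adjusted p = 0.000189; adjusted p = 0.244 with an estimated correlation), and LTi-like genes a median of 0.17 with 2 called (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.00399; adjusted p = 0.378 with an estimated correlation). Myeloid cell markers had a median of 0.53 with 0 of 11 called (2 higher adjusted over the list alone; adjusted p = 0.000486; adjusted p = 0.378 with an estimated correlation). In total 105 genes were called, 88 higher and 17 lower. Without WT 1, KO 2 or KO 3 the count was 30, 56 or 25; Il17a, Il17f, Gzmb, Gzmc, Ell2, Eprs, Hspa1a, Hspa1b and Ncoa7 stayed called in each. The authors' deposited table called 214 genes, with 83 shared, all in the same direction.

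In ILC1, type 1 cells of the tissue, the KO label went with a rise of Il17f from 1.02 ± 1.76 to 26.3 ± 11.6 CPM (log2 difference 1.4, SE 0.23, adjusted p = 0.00134). Slc16a10 (1.72, SE 0.28, adjusted p = 0.00134), Nup98 (1.36) and Cables1 (1.21) rose as they did in ILC3. Ncr1 (-1.43, SE 0.28, adjusted p = 0.015) and Ptpn6, which encodes the phosphatase SHP-1 (-1.11), were the falls. Both calls were lost without some library: Ncr1 without WT 1, WT 3, KO 1, KO 2 or KO 3 (-1.49 to -1.16) and Ptpn6 without KO 3 (-1.02). The stress list lay lower by a median of -0.49 with 0 of 20 called (5 lower adjusted over the list alone; adjusted p = 7.83e-05; adjusted p = 0.346 with an estimated correlation). LTi-like genes, with Il17f and the guidance receptor Nrp1 called, lay higher by 0.34 (2 adjusted over the list alone; adjusted p = 0.000652; adjusted p = 0.379 with an estimated correlation), and type 3 genes by 0.24 (1 called, 2 adjusted over the list alone; adjusted p = 0.0238; adjusted p = 0.346 with an estimated correlation). ILC1-associated genes lay lower by a median of -0.38 with 0 of 15 called (1 lower adjusted over the list alone; adjusted p = 0.045; adjusted p = 0.437 with an estimated correlation). NF-kB target genes had Nfkb1 and Nfkb2 called of 18 (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0191; adjusted p = 0.437 with an estimated correlation). Nrp1 (1.3) was lost without WT 1, WT 2, KO 2 or KO 3 (1.12 to 1.27), Nfkb1 (1.29) without WT 3 or KO 3 (1.12 and 1.21) and Nfkb2 (0.91) without WT 1, WT 3, KO 1, KO 2 or KO 3 (0.75 to 0.99). In total 16 genes were called, 14 higher and 2 lower. Here too differences rose with transcript length (Spearman 0.2; median length 4149 bases for raised and 1858 for lowered genes), and with the trend removed all 15 calls with a known length were kept. The count was 6 without WT 1, 6 without WT 3, 10 without KO 1, 8 without KO 2 and 4 without KO 3. The authors' deposited table called 56 genes, 14 of them shared and in the same direction.

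In NK cells, the KO label went with higher Dgat1, an enzyme of triglyceride synthesis (1380 ± 230 against 514 ± 108 CPM, n = 3; log2 difference 1.41, SE 0.21, adjusted p = 0.000746), Slc16a10 (1.34), Pid1, an adaptor of insulin signalling (1.47), and Hey1, a Notch target without a read in the 3 WT libraries (1.15; the floor of 3 reads over that group is 0.304 CPM). Adamdec1, a secreted metalloprotease, had the largest rise (3.91, SE 0.62, adjusted p = 0.00102) with a wide spread of 1010 ± 1220 against 29.1 ± 46.1 CPM. The coat protein gene Copg2 (-1.54) and the muskelin gene Mkln1 (-1.24) were lower. These 7 calls held without any 1 library, while Ncr1 (-1.25, SE 0.28, adjusted p = 0.0211) was lost without WT 3 (-0.81), and Hspa1b (-1.55) without WT 3 (-1.46). Il17a had no read in any of the 6 NK libraries. Eomes (-0.07, adjusted p = 0.942) and Tbx21 (-0.09, adjusted p = 0.909), regulators of NK identity, did not pass.

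Markers of stroma and endothelium lay higher in NK KO by a median of 1.35, with 0 of 10 called over all genes and 6 higher adjusted over the list alone (adjusted p = 0.000138; adjusted p = 0.347 with an estimated correlation). ILC2-associated genes had a median of 0.47 and 1 of 8 called, Hey1 (4 higher adjusted over the list alone; adjusted p = 0.0172; adjusted p = 0.128 with an estimated correlation). The stress list had 3 of 20 lower, Hspa1a, Hspa1b and Jun, and a median of -0.48 (5 lower adjusted over the list alone; adjusted p = 0.000138; adjusted p = 0.347 with an estimated correlation). Hspa1a (-1.47) was lost without WT 2 (-1.19) or WT 3 (-1.42), and Jun (-1.07) without WT 1, WT 3, KO 2 or KO 3 (-0.98 to -0.81). The total was 159 genes, 99 higher and 60 lower. This count is the least settled of the 4: it was 428 without WT 1, 309 without WT 2, 31 without WT 3, 361 without KO 1, 84 without KO 2 and 249 without KO 3. Quantile normalisation gave 80 genes (59 higher and 21 lower) and limma-voom 2 (2 higher and 0 lower), with Dgat1 (1.51) the 1 call left of the 7 named above. Limma with library weights and limma on the NK libraries alone called 0, against 1722 genes at an unadjusted p under 0.05 in the fit of all libraries, so all 7 calls end under these 2 settings. With the stress score as a covariate, chosen after seeing the data, Slc16a10 (0.81) and Hey1 (1.05) were not called. The authors' deposited table called 295 genes, 105 of them shared, all in the same direction. It had 144 higher and 151 lower, so the balance toward rises is not seen there.

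Whether the KO effect differs between subsets was tested against the effect in CCR6-positive ILC3. Against NK cells 2 genes passed: Il17f (-2.62, SE 0.32, adjusted p = 1.47e-05) and Il17a (-2.36, SE 0.38, adjusted p = 0.0025), which had no reads or 1 read in NK cells. The count was 21 without NK WT 1, 8 without NK WT 2, 6 without NK KO 1 and 8 without NK KO 3. Limma-voom on the recovered reads called 0, with Il17f at -3.42 and Il17a at -4, so both calls end under it; limma had 841 genes at an unadjusted p under 0.05. For ILC1 limma called 0 genes, with 288 at an unadjusted p under 0.05, and 1 without ILC1 KO 3; limma-voom called 0. For CCR6-negative ILC3 limma called 0, with 128 at an unadjusted p under 0.05, and limma-voom 0. The fall of Ncr1 did not differ by this test from its value in CCR6-positive ILC3 (differences of -1.26 in NK cells, -1.43 in ILC1 and -1.19 in CCR6-negative ILC3, adjusted p = 0.371, 1 and 1). In simulations of these 3 tests changes of 2 were recovered for 80%, 75% and 73% of genes, and changes of 1 for 16%, 14% and 8%. At camera's preset correlation 0 lists were called for NK cells, 4 for ILC1 and 3 for CCR6-negative ILC3. With an estimated correlation 0 were called in each. Of these lists the stress list is given here. By camera, the fall of immediate early and stress genes was weaker in ILC1 (0 of 20 called, 0 also adjusted over the list alone; adjusted p = 0.00182; adjusted p = 0.494 with an estimated correlation) and in CCR6-negative ILC3 (0 of 20 called, 0 also adjusted over the list alone; adjusted p = 0.0171; adjusted p = 0.818 with an estimated correlation) than in CCR6-positive ILC3.

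Genes called with the KO label were shared between subsets. Of 326 genes called in any subset, 77 were called in the same direction in at least 2 subsets (68 higher and 9 lower) and 0 in opposite directions. The 7 genes higher in all 4 subsets were Cables1, Dgat1, Epas1 (a hypoxia-inducible factor), Foxo1 (a regulator of lymphocyte survival and trafficking), Nfkb1, Nup98 and Slc16a10. At an adjusted p under 0.1 there were 12 such genes and under 0.01 there was 1, and with library weights, or on the NK libraries alone, limma called 0 NK genes, so no gene is shared by all 4 subsets under these settings. Leaving out each of the 24 libraries in turn, Cables1 stayed higher in all 4 subsets 24 times, Nup98 and Slc16a10 22, Dgat1 20, Nfkb1 19, Foxo1 14 and Epas1 7; 3 of the 7 genes were left without NK WT 3, ILC1 WT 3, ILC1 KO 3 or CCR6-positive KO 3. Slc16a10 kept its call in NK cells, ILC1 and CCR6-negative ILC3 without any 1 library; in CCR6-positive ILC3 it was lost without WT 2 (1.12) or KO 3 (1.25). Epas1 and Foxo1 had differences of 0.81 to 1.24. Gzmc, Il17f, the TGF-beta mediator Smad3 and 7 others were higher in 3 subsets, and Hspa1a, Hspa1b, Jun and Ncr1 lower in 3. CCR6-negative and CCR6-positive ILC3 shared 64 higher genes, where 1.08 are expected of independent calls, and 6 lower genes, where 0.04 are expected. Any difference between the mice of the 2 labels that reaches several subsets would also give shared calls. The expected numbers are thus no baseline for a Bcl6 effect. All 105 genes called in CCR6-positive ILC3 had the same direction in CCR6-negative ILC3, against 66.8% of all genes for this pair. Of the genes called in NK cells 122 (76.7%) had the same direction in CCR6-negative ILC3, against 60% of all genes. Gimap, Klra, Klrb1, Ccl3, Gzm, H2 and Hspa1 genes belong to families whose members share sequence, so their values are uncertain.

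Genes that Bcl6 represses in T and B cells did not shift as a list with the KO label in any subset. Of 19 tested members Runx3 and Ccnd2, regulators of lymphocyte fate and division, were higher in NK KO (4 higher and 2 lower adjusted over the list alone; adjusted p = 0.421), 0 were called in ILC1 (1 higher adjusted over the list alone; adjusted p = 0.484), the cytokine signal inhibitor Cish was higher in CCR6-negative KO (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.739) and Cish was higher and the trafficking regulator Klf2 lower in CCR6-positive KO (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.468). The medians were 0.08, 0.02, 0.1 and 0.14. The fall of Klf2 (-1.35) was lost without WT 1, WT 3 or KO 3 (-1.3 to -1.17). Whether the calls of Runx3, Ccnd2 and Cish hold when 1 library is left out is not given here. B and plasma cell markers did not shift either (adjusted p = 0.541, 0.418, 0.739 and 0.67).

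**Figure D1:**
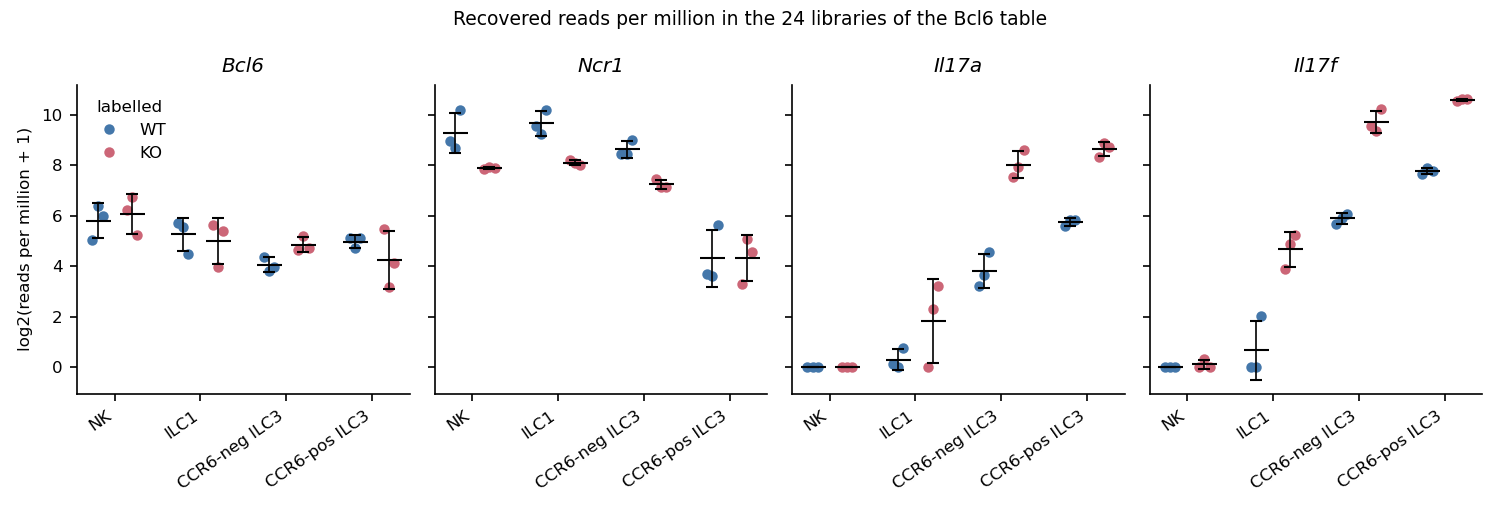
Points are the 3 libraries of each subset and label, as log2(CPM + 1), with bars for mean and SD of the plotted values. Il17f in CCR6-positive ILC3 averaged 1550 CPM in KO and 216 CPM in WT, while Bcl6 reads overlap between the labels in all subsets but CCR6-negative ILC3.

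CCR6-positive and CCR6-negative ILC3 were compared in both tables, which asks what sets the LTi-like subset apart from the subset with type 1 features. In WT libraries of the Bcl6 table CCR6-positive cells were higher in Ccr6, the chemokine receptor used to sort them (2.95, SE 0.31, adjusted p = 5.37e-08), Cd4 (3.69), the antigen presentation genes Cd74 (3.92), H2-Aa (3.64) and H2-Eb1 (3.5), the growth factor gene Vegfa (2.36) and the tetraspanin Cd81 (2.61). They were lower in Ifng (-2.94, SE 0.24, adjusted p = 7.21e-11), Ncr1 (-3.11), the gut-homing receptor Ccr9 (-3.67), the cathepsin Ctsw (-3.2), the type 1 regulator Tbx21 (-1.87) and Prdm1 (-1.32). Il17f was higher (1.42). LTi-like genes had 12 of 19 higher and a median of 1.15 (16 higher and 1 lower adjusted over the list alone; adjusted p = 2.03e-25 and 0.000359 with an estimated correlation). Type 1 effector genes had 9 of 20 lower and the type 1 module of CCR6-negative ILC3 11 of 20 (medians -0.91 and -0.97; 14 lower in each adjusted over the list alone; adjusted p = 7.43e-25 and 7.44e-22). Bcl6-repressed genes had 1 higher and 5 lower (2 and 8 adjusted over the list alone; adjusted p = 0.00135) and trafficking genes 1 higher and 4 lower, with Ccr9 and Ccr2 among the falls (2 and 7 adjusted over the list alone; adjusted p = 0.000464). Stress genes lay higher by 0.47 with 4 of 20 called (7 higher adjusted over the list alone; adjusted p = 0.000171; adjusted p = 0.121 with an estimated correlation), and cell cycle genes lower by -0.27 with 2 of 17 called (3 lower adjusted over the list alone; adjusted p = 0.005; adjusted p = 0.121 with an estimated correlation). The total was 492 genes, 242 higher and 250 lower, and it was 301 without CCR6-negative WT 3 and 307 without CCR6-positive WT 2.

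In the wild-type SI libraries, 3 of each subset, the same comparison called 945 genes, 433 higher and 512 lower. Ccr6 (5.09, SE 0.48, adjusted p = 8.85e-06), Cd4 (3.95), Ccr7, a receptor for entry to lymph nodes (3.92), and H2-Aa (3.15) were higher in CCR6-positive cells. Ncr1 (-4.61, SE 0.26, adjusted p = 5.64e-08), Nkg7 (-4.62), Ifng (-4.59), Ctsw (-4.54) and Ccr9 (-3.71) were lower, and so was Prdm1 (-2.67). LTi-like genes had 10 of 20 higher (median 1.26, 14 adjusted over the list alone, adjusted p = 3.2e-17 and 0.00684 with an estimated correlation), the type 1 module 15 of 20 lower (median -2.54, 17 adjusted over the list alone, adjusted p = 1.14e-30) and interferon response genes 1 higher and 5 lower (median -0.5, 2 and 8 adjusted over the list alone, adjusted p = 1.22e-05). T cell markers lay lower with 1 called (1 adjusted over the list alone; adjusted p = 0.0496; adjusted p = 0.297 with an estimated correlation). Within each of the 3 correction sets, 945, 945 and 944 of the calls had the same direction. The calls were chosen on these same libraries, and 943 of the 945 had values that do not overlap between the subsets. Their direction within a set was thus fixed in advance and is no separate check of batch. The count was 577 without CCR6-negative 3 and 513 without CCR6-positive 3. The authors' deposited table called 833 genes, with 772 shared.

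Between the tables, the log2 differences of 10248 genes correlated at 0.67 (Pearson) and 0.5 (Spearman), a description across genes, which are not independent replicates. All 349 genes called in both tables had the same direction.

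**Figure D2:**
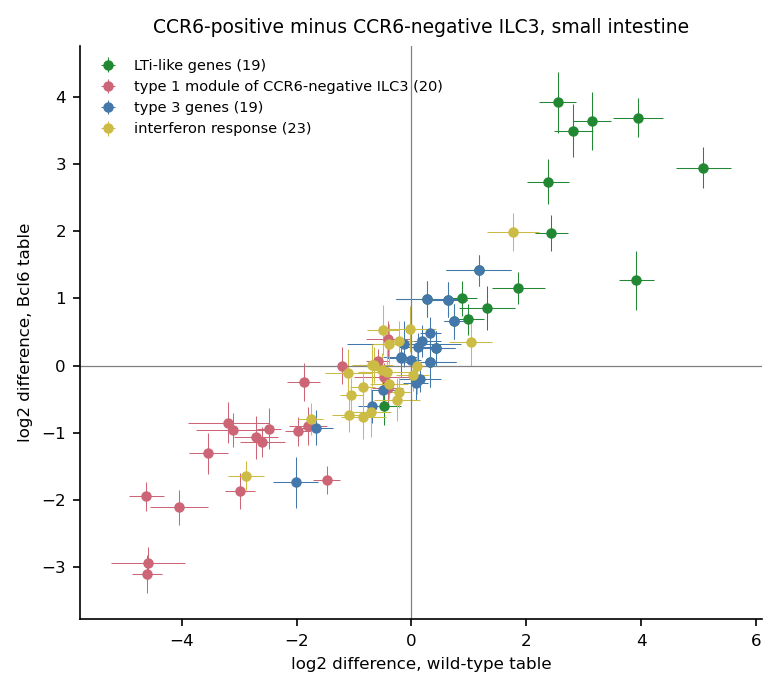
Each point is a list member with its log2 difference between CCR6-positive and CCR6-negative ILC3 of the small intestine in the wild-type table (horizontal axis) and the Bcl6 table (vertical axis), with SE bars. The 19 LTi-like genes lie mostly at the upper right and the 20 genes of the type 1 module mostly at the lower left.

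ILC1 and NK cells were compared to find what separates the 2 type 1 subsets. In WT libraries of the Bcl6 table ILC1 were higher in the IL-22 gene Il22 (5.04, SE 0.37, adjusted p = 8.77e-13), Tnfsf11, which encodes RANKL and had no read in the NK libraries (4.45), Il7r, the receptor of IL-7 (3.86), Serpinb1a (3.93) and the retention receptor Cxcr6 (3.23). NK cells were higher in Gzma (-5.2, SE 0.27, adjusted p = 1.37e-16), Eomes (-4.23), the integrin Itgam (-2.95) and the Klra receptor genes, whose reads can be shared, such as Klra7 (-3.94). Tbx21 did not pass (-0.43, adjusted p = 0.406). NK-associated genes had 16 of 18 lower (median -1.96, 17 adjusted over the list alone, adjusted p = 8.55e-36 and 0.000261 with an estimated correlation), type 3 genes 12 of 19 higher (median 1.58, 12 higher and 1 lower adjusted over the list alone, adjusted p = 9.09e-19) and ILC1-associated genes 8 higher and 1 lower (median 1.02, 9 and 1 adjusted over the list alone, adjusted p = 8.1e-13). T cell markers had 2 of 4 lower, Cd3d and Cd3g (2 adjusted over the list alone; adjusted p = 0.0203; adjusted p = 0.136 with an estimated correlation). The total was 799 genes, 522 higher and 277 lower, 551 to 953 without any 1 library, 316 in a fit of the compared groups alone and 350 by limma-voom. In the wild-type table, with 2 libraries of each and all 4 in the third correction set, 672 genes were called, 439 higher and 233 lower. Plekhg1 (7.28), Il23r (5.13) and Il7r (4.05) were higher in ILC1 and Klra18 (-4.96) and Eomes (-4.58, SE 0.78, adjusted p = 0.00245) in NK cells. The count was 388 without ILC1 4 and 317 without the 2 libraries with Y-linked reads. ILC2-associated genes had a mean value of 8.23 in NK 4 against 5.35 in NK 3, and of 6.07 and 6.35 in ILC1. Limma on these 4 libraries alone called 0 genes, against 2737 at an unadjusted p under 0.05 in the fit of all libraries, so every call of this comparison ends in that fit. The authors' deposited table called 692 genes, 561 of them shared. Across 10248 genes the tables correlated at 0.51 (Pearson) and 0.35 (Spearman), and 279 of the 281 genes called in both had the same direction.

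CCR6-negative ILC3 and ILC1, which share surface features, were compared in WT libraries of the Bcl6 table. CCR6-negative ILC3 were lower in the chemokine genes Ccl5 (-4.78, SE 0.21, adjusted p = 1.44e-18), Ccl4 (-4.17), Ccl3 (-4.13) and Xcl1 (-3.71), in Klrd1, part of an inhibitory NK receptor (-4.23), and in Il12rb2, a receptor chain for IL-12 (-3.35). Higher were Pcp4, a calmodulin-binding protein (3.21, SE 0.27, adjusted p = 6.9e-11), Il22 (2.13), Il17f (2.12), the receptor kinase Ret (2.09) and Arg1 (2.06). The type 1 module had 15 of 20 lower (median -2.22, 1 higher and 16 lower adjusted over the list alone, adjusted p = 1.45e-51) and type 1 effector genes 16 of 20 (median -2.04, 1 and 18 adjusted over the list alone, adjusted p = 1.53e-50), both also called with an estimated correlation (adjusted p = 2.97e-06). Type 3 genes had 7 higher and 1 lower (median 0.52, 9 and 2 adjusted over the list alone, adjusted p = 4.05e-07). LTi-like genes had 8 higher and 4 lower (9 and 6 adjusted over the list alone; adjusted p = 0.0012; adjusted p = 0.231 with an estimated correlation). The total was 382 genes, 141 higher and 241 lower; it was 245 without ILC1 WT 1, 206 without ILC1 WT 2, 224 without CCR6-negative WT 1 and 221 without CCR6-negative WT 3. Differences fell with transcript length (Spearman -0.27; median length 2536 bases for higher and 3655 for lower genes), and with the trend removed 307 of the 361 calls with a known length were kept.

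Each SI subset of the wild-type table was then set against the mean of the other 4 to find its signature. NK cells had 2649 called genes, 1229 higher and 1420 lower. Eomes (6.93, SE 0.62, adjusted p = 9.12e-07), Ccl5 (5.55), Gzma (5.38) and the signalling adaptor Tyrobp (5.34) were higher; Plekhg1 (-7.18), Il22 (-5.5), Il23r (-5.22) and Il7r (-4.32) were lower. NK-associated genes had 16 of 18 higher (median 3.61, 16 adjusted over the list alone, adjusted p = 1.97e-18), the type 1 module 17 of 20 (median 3.17, 17 adjusted over the list alone, adjusted p = 5.22e-19) and LTi-like genes 1 higher and 16 lower (median -2.01, 1 and 17 adjusted over the list alone, adjusted p = 7.41e-14), all 3 also with an estimated correlation. NF-kB target genes had 10 of 18 lower (median -0.75, 1 higher and 12 lower adjusted over the list alone, adjusted p = 1.08e-07; adjusted p = 0.116 with an estimated correlation). Bcl6 itself was higher in NK cells (1.04, adjusted p = 0.0138), a call lost without NK 3 (0.72). The count was 1653 without NK 4 and 1392 with the correction sets as batch term. The 2 NK libraries differed in the mean value of ILC2-associated genes, with 8.23 in NK 4 and 5.35 in NK 3. That mean was 10.57 in both SI ILC2 libraries. The source of the difference was not tested, and NK 4 also enters the signatures of the other SI subsets.

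ILC1 had 1386 called genes, 765 higher and 621 lower. Higher were Il12rb2 (4.74, SE 0.29, adjusted p = 1.74e-07), Klrd1 (4.43), Ccl5 (4.31), Xcl1 (4.25), Fasl, a death ligand (3.89), Tbx21 (3.84) and Ifng (3.73), and lower were Il17a (-3.33) and Ret (-3.38). The type 1 module had 19 of 20 higher (median 3.21, 19 adjusted over the list alone, adjusted p = 7.14e-35), type 1 effector genes 16 (median 2.73, 17 adjusted over the list alone, adjusted p = 1.97e-27), ILC1-associated genes 6 (median 0.76, 11 higher and 1 lower adjusted over the list alone, adjusted p = 1.96e-06) and LTi-like genes 1 higher and 10 lower (1 and 11 adjusted over the list alone, adjusted p = 9.12e-08), all 4 also with an estimated correlation. T cell markers had 2 of 8 higher, Cd3e and Trat1 (median 1.11, 5 adjusted over the list alone, adjusted p = 0.00817; adjusted p = 0.166 with an estimated correlation), and both calls were lost without ILC1 4 (1.15 and 2.29) and that of Trat1 also without ILC1 3 (1.71). The count was 534 without ILC1 4, 624 without the 2 libraries with Y-linked reads and 529 with the correction sets as batch term.

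ILC2 had 2232 called genes, 1003 higher and 1229 lower. Higher were the heparan sulfate enzyme gene Hs3st1 (7.51), the type 2 cytokine gene Il13 (7.23, SE 1.02, adjusted p = 9.94e-05), Il17rb, a receptor for IL-25 (6.56), Klrg1 (6.09), Calca (5.13), Gata3, the regulator of this lineage (4.19, SE 0.26, adjusted p = 1.42e-08), and Areg (3.9). Il5 was higher too (6.61), a call lost without ILC2 2 (6.12). Lower were Klrb1b (-7.43), Klrk1 (-6.85), Il23r (-6.14) and Ncr1 (-4.87). ILC2-associated genes had 18 members higher (median 4.8, 19 adjusted over the list alone, adjusted p = 3.63e-25) and the type 1 module 1 higher and 18 lower (median -3.73, 1 and 18 adjusted over the list alone, adjusted p = 2.92e-24), both also with an estimated correlation. Interferon response genes had 7 of 25 higher and 1 lower (median 0.28, 8 and 1 adjusted over the list alone, adjusted p = 0.0141; adjusted p = 0.276 with an estimated correlation). A shift of library medians turned the balance to 1396 higher and 936 lower of 2332 calls. The count was 1322 without ILC2 1, 864 without ILC2 2 and 1189 with the correction sets as batch term.

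CCR6-negative ILC3 had 1748 called genes, 1089 higher and 659 lower. Higher were Pcp4 (6.19, SE 0.28, adjusted p = 7.68e-10), Il22 (6.15), Il23r (5.01), Il1r1, the IL-1 receptor (4.14), Tnf (3.36) and Ncr1 (2.71), and lower were the costimulatory receptor Cd27 (-4.31) and Tigit (-3.28). Type 3 genes had 13 of 20 higher and 1 lower (median 1.54, 16 and 1 adjusted over the list alone, adjusted p = 4.03e-14 and 0.000523 with an estimated correlation). NF-kB target genes had 8 of 18 higher (median 0.55, 9 adjusted over the list alone, adjusted p = 5.01e-08; adjusted p = 0.171 with an estimated correlation), and NK-associated genes 11 of 18 lower (median -1.33, 15 adjusted over the list alone, adjusted p = 3.26e-11; adjusted p = 0.0766 with an estimated correlation). The count was 1124 without CCR6-negative 2, 946 without CCR6-negative 3 and 1102 with the correction sets as batch term.

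CCR6-positive ILC3 had 3340 called genes, 1874 higher and 1466 lower. Higher were Ccr6 (6.8, SE 0.39, adjusted p = 4.23e-09), Il22 (6.55), the prostaglandin synthase Ptges (5.71), Cxcr5, a receptor for B cell follicles (5.53), Il1r1 (5.07) and Nrp1 (4.65), and lower were Nkg7 (-6.96), Gzma (-6.24), Ifng (-4.96), Tbx21 (-3.75) and Prdm1 (-2.4). LTi-like genes had 19 of 20 higher (median 3.02, 19 adjusted over the list alone, adjusted p = 1.37e-23 and 0.00574 with an estimated correlation) and type 1 effector genes 1 higher and 13 lower (median -3.74, 2 and 13 adjusted over the list alone, adjusted p = 6.13e-14). Interferon response genes had 3 of 25 higher and 8 lower (median -0.41, 3 and 9 adjusted over the list alone, adjusted p = 0.00289; adjusted p = 0.159 with an estimated correlation), and cell cycle genes 1 higher and 4 lower of 22 (1 and 4 adjusted over the list alone, adjusted p = 0.00627; adjusted p = 0.153 with an estimated correlation). The count was 2217 without CCR6-positive 2 and 1935 without CCR6-positive 3.

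LI and SI were compared as the mean over ILC2 and both ILC3 subsets, which asks what the tissue adds to the subset. Higher in the LI were Cd28, a costimulatory receptor (chromosome 1, 60716800 to 60773359, mm10; 4.38, SE 0.25, adjusted p = 7.2e-08), the calcium-binding protein genes S100a6 (4.06) and S100a4 (3.53), the protease inhibitor Ctla2a (3.53), Ccr7 (2.76) and Klrk1 (1.68). Values per subset stand behind the means of the last 2, without a test between subsets: Klrk1 differed by 4.6 in ILC2 and by 0.38 and -0.04 in CCR6-negative and CCR6-positive ILC3, and Ccr7 by 0.7 in ILC2 and by 4.41 and 3.45. Lower were the small-intestinal homing receptor Ccr9 (-3.78, SE 0.21, adjusted p = 7.2e-08), the short-chain fatty acid receptor Ffar2 (-3.44), the ATP receptor P2rx7 (-2.84) and Gimap7 (-2.76). Genes of the epithelium also moved: the mucin Muc2 (3.51) and the epithelial defence gene Lypd8 (4.35) were higher and the gastric-type mucin Muc6 (-5.71) and Tff2 (-5.76) lower. Epithelium markers had 5 of 14 higher (median 0.6, 5 adjusted over the list alone, adjusted p = 0.00389; adjusted p = 0.471 with an estimated correlation). Interferon response genes had 7 of 25 lower (median -0.38, 9 lower adjusted over the list alone, adjusted p = 8.91e-05; adjusted p = 0.382 with an estimated correlation). Stress genes had 2 higher and 7 lower (median -0.53, 5 and 10 adjusted over the list alone, adjusted p = 0.00136; adjusted p = 0.405 with an estimated correlation). In this list Jun differed by -2.72 and -2.74 in the CCR6-negative and CCR6-positive pair of the first correction set and Zfp36 by -2.56 and -2.67. In ILC2 the sets disagreed, with -0.38 and 1.1 for Jun and -0.78 and 1.37 for Zfp36 in the first and second set. Every LI and SI pair within a set also crosses the library series. The SL library is the SI one in the first set and the LI one in the second. Set, series and subset cannot be told apart here, and whether the subsets differ was not tested. Within correction sets Cd28 differed by 5.39 and 5.71 in ILC2, 5.03 in CCR6-negative and 3.35 in CCR6-positive ILC3, and Ccr9 by -5.14, -4.66, -4.02 and -2.24, 1 library against 1. The total was 1182 genes, 707 higher and 475 lower; 707 of the 1182 (59.8%) had the same direction in all 4 such pairs. With the sets as batch term 580 genes were called, 558 of them shared, and 493 without SI ILC2 2. With the numbers in the titles as a block 4 genes were called; under it steady-state LI and SI share a level through the SL libraries alone. A shift of library medians, which moved the median of all genes by -0.103, gave 488 higher and 841 lower of 1329, so the balance of rises and falls is not settled. The epithelium score as a covariate, chosen after seeing the data, left 502 of the 1182 calls.

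In ILC2 alone, with 2 libraries of each tissue, S100a4 (5.63, SE 0.37, adjusted p = 2.75e-07), Cd28 (5.55), the reductase gene Msrb3 (5.43), Klrk1 (4.6), Capg (4.07) and the chemokine receptor Ccr2 (4.07) were higher in the LI, and Gzma (-7.16, SE 0.84, adjusted p = 0.000108) and Ccr9 (-4.9) lower. Interferon response genes had 6 of 25 lower, with Igtp (-2.21) and Gbp2 (-1.68) in their number (median -0.94, 11 lower adjusted over the list alone, adjusted p = 3.36e-14 and 0.0192 with an estimated correlation). Gbp2 belongs to a family with shared reads. NF-kB target genes had 3 of 18 higher (median 0.45, 5 adjusted over the list alone, adjusted p = 0.000208; adjusted p = 0.505 with an estimated correlation). Tbx21 was lower (-2.09, adjusted p = 0.00131), a call lost without SI ILC2 2 (-1.78). All 367 calls, 217 higher and 150 lower, had the same direction in both correction sets. All 367 also had values that do not overlap between the tissues, so their direction within a set was fixed in advance. The count was 188 without SI ILC2 1, 148 without SI ILC2 2, 188 without LI ILC2 1, 205 without LI ILC2 2 and 228 with the sets as batch term. A shift of library medians moved the median of all genes by -0.122 and gave 162 higher and 215 lower of 377. The authors' deposited table called 414 genes, 324 of them shared.

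Infection with C. rodentium, which attaches to the colon wall, was compared with steady state as the mean over the 3 LI subsets. Atp1b2, a subunit of the sodium pump (chromosome 11, 69599736 to 69605942, mm10), rose most (6, SE 0.48, adjusted p = 9.87e-06): the 4 infected libraries held values of 11.34 to 14 and the 16 others 4.27 to 9.19. The cholesterol exporter Abca1 rose too (3.01, SE 0.22, adjusted p = 4.57e-06), and so did Neto2 (2.46), Gimap7 (2.14), the transcriptional regulator Spen (2.07), Klrd1 (1.89), the mitochondrial iron importer Slc25a37 (1.73), the mRNA decay factor Zfp36 (1.31) and Gbp2 (1.28). Cables1 (-1.63), the GTPase activator Dlc1 (-1.33) and the phosphatase Bpnt1 (-1.4) fell. Tnf (1.01, adjusted p = 0.0466) was lost without CCR6-negative infected 2 (0.92) or LI ILC2 1 (0.94), and Thbd (-1.57) and Tmem119 (-1.8) without LI ILC2 1 (-1.42 and -1.7). Interferon response genes had 2 of 25 higher, Gbp2 among them (median 0.47, 10 higher adjusted over the list alone, adjusted p = 8.74e-07; adjusted p = 0.164 with an estimated correlation). Stroma and endothelium markers lay lower with 0 of 12 called (median -1.98, 0 adjusted over the list alone, adjusted p = 0.00108; adjusted p = 0.583 with an estimated correlation), and epithelium markers likewise with 0 of 14 (median -0.37, 2 lower adjusted over the list alone, adjusted p = 0.0304; adjusted p = 0.583 with an estimated correlation). Stress genes had Zfp36 called (median 0.3, 6 and 2 adjusted over the list alone, adjusted p = 0.00101; adjusted p = 0.526 with an estimated correlation).

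The infection comparison called 56 genes, 23 higher and 33 lower. Within correction sets, 1 library against 1, Atp1b2 differed by 5 in ILC2 and 8.79 in CCR6-negative ILC3, Abca1 by 2.72 and 4.78, Klrd1 by 2.3 and 2.28 and Gbp2 by 2.17 and 0.6; of the 56 genes 43 had the same direction in ILC2 and 56 in CCR6-negative ILC3. In ILC2 Gimap7 (-0.09), Zfp36 (-0.25), Bpnt1 (0.77) and Thbd (0.11) differed the other way from the mean. The pairs also cross the library series, in opposite directions, so set, series and subset cannot be told apart there. CCR6-positive ILC3 had no such pair, and across sets their Atp1b2 differed by 4.43. The count was 123 without CCR6-negative infected 2, 129 without CCR6-negative infected 1, 21 without LI ILC2 1, 315 without LI ILC2 2 and 3 with the sets as batch term, Atp1b2, Abca1 and Slc25a37. With the numbers in the titles as a block limma called 0, against 2374 at an unadjusted p under 0.05 without it, and these 3 calls ended too, at 6.68, 3.15 and 1.88; under this block infected and steady-state LI share a level through the SL libraries alone. Quantile normalisation gave 24 genes, 17 higher and 7 lower. The authors' deposited table, which tests each subset alone, called 36 genes in CCR6-negative ILC3, 2 in CCR6-positive ILC3 and 10 in ILC2.

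**Figure D3:**
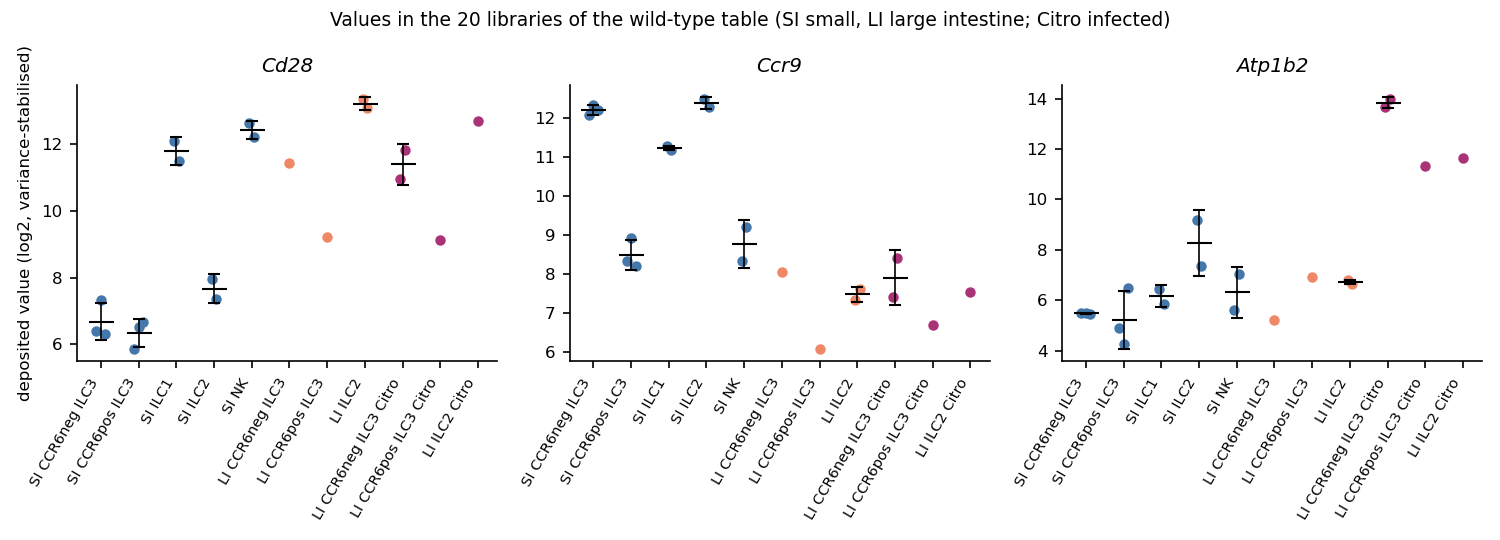
Points are the deposited log2-scale values of Cd28, Ccr9 and Atp1b2 in the 20 libraries of the wild-type table by group, with bars for mean and SD where a group has more than 1 library. Atp1b2 lies at 11.34 to 14 in the 4 infected libraries and at 4.27 to 9.19 in the 16 others.

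In all, 370 pairs of list and comparison were tested, 126 were called at the preset correlation and 43 with an estimated one, all 43 among the 126. Not every called list is named above. Stroma and endothelium markers were called in 4 comparisons, T cell markers in 4 and myeloid cell markers in 3. With an estimated correlation 0 of these held. Immediate early and stress genes had the most calls, 15 of 20 comparisons, of which 1 held with an estimated correlation. B and plasma cell markers did not pass in any of the 20 comparisons, nor did the 6 tested mast cell markers in the 10 of the wild-type table. Mast cell markers had too few tested members in the Bcl6 table, and red blood cell markers, with 1 tested member, had no test in either table.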

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

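Of the tests in this part, those of carried-over cells, of transcript length and of the stress score were chosen only after the results were seen.

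The KO effect on 2 genes differed between NK cells and CCR6-positive ILC3: Il17a by -2.36 and Il17f by -2.62 on the log2 scale, calls that ended under limma-voom at -4 and -3.42. NK cells held no Il17a read in any of 6 libraries and 1 Il17f read in 1 of them, so the difference is the rise of both cytokine genes in CCR6-positive ILC3, seen in 3 of 3 KO libraries. It says that the genes were not switched on in NK cells, a subset that does not make these cytokines here under either label. Of the 100 splits tested for this comparison, 30 gave at least 2 genes and the highest 333, so chance is not excluded for the number of genes. The split with 333 genes exchanges the labels of all 6 NK libraries and leaves those of CCR6-positive ILC3, so it adds the 2 KO effects instead of subtracting them. The subsets share 13 higher and 4 lower calls, and which effects make up the 333 genes was not tested.

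The rises in CCR6-positive ILC3 call for a closer look, because these cells held 23.7 CPM of Ncr1, the gene that drives the Cre, and gene-level Bcl6 did not pass, with 2 KO libraries below every WT library (8.03 and 16.2 CPM) and KO 1 above them (42.8 CPM). Carried-over CCR6-negative ILC3, taken at the highest ratio of Ncr1 between the subsets in any library (23.7%), could not supply them: 83 of 88 raised genes rose by more than the whole carried level, with 1330 against 204 CPM for Il17f and 350 against 64.4 CPM for Il17a. Differences rose with transcript length here too (Spearman 0.2, median length 4697 bases for raised and 2803 for lowered genes). Once each library's trend on length was removed, 98 of the 104 calls with a known length stayed called in the same direction. The trend thus accounts for few of these calls, while a length effect beyond it was not tested. In CCR6-negative ILC3, with 107 of 147, the trend stays open. With the stress score as a covariate in limma, Il17f stayed at 2.32 (SE 0.35, adjusted p = 0.000801) and Il17a at 1.79 (SE 0.41, adjusted p = 0.0227). The slope of the score is fitted over all 24 libraries, among them NK libraries with 0 or 1 Il17f reads. It may thus be too flat for CCR6-positive ILC3, so this does not exclude a lower stress state of the KO libraries. For the other 103 calls it may explain part, because 19 stayed called while their median size went from 1.12 to 0.96 and the median SE from 0.23 to 0.35. The scores ran from 12.27 to 12.68 in KO and from 13.16 to 13.52 in WT, so label and stress cannot be parted. In CCR6-negative ILC3 they also lay apart, at 12.02 to 12.41 in KO and 12.69 to 12.81 in WT. The same was seen in ILC1, at 12.01 to 12.42 in KO and 12.5 to 12.78 in WT. Label and stress cannot be parted in these 2 subsets either.

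Several candidate explanations remain for Il17a and Il17f. The first is loss of Bcl6 in CCR6-positive cells with past or low Ncr1 expression. Another is an effect of deletion in other Ncr1-expressing cells on the tissue. An effect of Cre or of the Ncr-Cre allele, which WT mice lack, remains as well. So do a difference between the mouse cohorts and a lower stress state of the KO libraries. The reads carried over from CCR6-negative cells (83 of 88 genes above them) are not one. No test here parts those that remain. A count of reads over the deleted Bcl6 exons would show the first.

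The rise of Il17f was also seen in ILC1, in 3 of 3 KO libraries, from 1.02 to 26.3 CPM. That is a low level beside 860 CPM in CCR6-negative KO, and carried-over ILC3 in the ILC1 sort were not tested. Ncr1 fell in NK cells, ILC1 and CCR6-negative ILC3; in CCR6-positive ILC3, where it is low, it did not pass, and the test of a difference between subsets did not pass either. The Ncr-Cre allele itself was not measured apart from the deletion, so the fall cannot be assigned to Bcl6.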

How the results depend on the processing

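Alternatives are grouped by setting, with the number of called genes; those chosen after the data were seen are named so, and where no cause is given the cause was not tested.

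The filter moved the KO counts. Without a filter they were 8 in ILC1, 69 in CCR6-negative ILC3 and 64 in CCR6-positive ILC3, the difference of NK cells from CCR6-positive ILC3 had 20 genes and infection 24. With the stricter filter the KO counts were 50 in NK cells, 29 in ILC1, 255 in CCR6-negative ILC3 and 175 in CCR6-positive ILC3. Among scalings, quantile normalisation gave 80 genes for KO in NK cells and 24 for infection, and a shift of medians 34 for infection. Without the variance trend KO called 5 genes in ILC1, 53 in CCR6-negative ILC3 and 43 in CCR6-positive ILC3, LI against SI 757 and infection 6.

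With library weights (arrayWeights) KO called 0 genes in NK cells, 45 in ILC1, 918 in CCR6-negative ILC3 and 461 in CCR6-positive ILC3. The ILC1 difference had 1 gene, the WT ILC3 subsets 832 and CCR6-negative ILC3 against ILC1 730. In the wild-type table the SI ILC3 subsets had 1963, ILC1 against NK cells 339, LI against SI 2156 and in ILC2 587. A fit of the compared groups alone gave 0 genes for KO in NK cells, 3 in ILC1 and 45 in CCR6-positive ILC3, and 316 for WT ILC1 against NK cells. It gave 1855 for the SI ILC3 subsets, 0 for SI ILC1 against NK cells (limma, 2 libraries each), 2595 for LI against SI, 1128 in ILC2 and 410 for infection.

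With the replicate number as a block, KO called 282 genes in NK cells, 32 in ILC1, 242 in CCR6-negative ILC3 and 183 in CCR6-positive ILC3; within the genotype the differences of NK cells and ILC1 from CCR6-positive ILC3 had 6 and 3. After group means were removed, 4 to 6 of the 6 libraries of a comparison correlated best with the library of their own number, 6 for KO in ILC1 and in CCR6-negative ILC3 and for WT ILC1 against NK cells, at -0.02 to 0.25 per pair; the labels do not say whether a number marks a pair. A block of title numbers in the wild-type table, with the SL series, which has none, as its own level, gave 1531 for SI NK cells, 651 for SI ILC1, 1448 for SI ILC2, 4 for LI against SI, 147 in ILC2 and 0 for infection. Under this block steady-state LI and SI share a level through the SL libraries alone. Limma-voom on recovered reads gave 2 genes for KO in NK cells, 36 in ILC1, 489 in CCR6-negative ILC3 and 281 in CCR6-positive ILC3, 0 for the NK difference, 350 for WT ILC1 against NK cells and 605 for CCR6-negative ILC3 against ILC1. It shifted the median of all genes by -0.145 and -0.136 in the NK and ILC1 differences and by 0.162 in ILC1 against NK cells.

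Other batch terms moved infection to 15 genes without a term and 29 with 3 library series. Without the SL libraries, 1177 genes were called for SI ILC2, 1034 for SI CCR6-negative ILC3, 465 for the SI ILC3 subsets, 407 for SI ILC1 against NK cells, 80 for LI against SI in ILC2 and 112 for infection. The settings chosen after the data were seen follow. The correction sets as batch term gave 1392 for SI NK cells, 529 for SI ILC1, 1189 for SI ILC2, 1102 for SI CCR6-negative ILC3, 599 for the SI ILC3 subsets, 369 for SI ILC1 against NK cells, 580 and 228 for LI against SI (mean and ILC2) and 3 for infection. Without the 2 libraries with Y-linked reads SI ILC1 had 624 genes and ILC1 against NK cells 317. Without the 2 NK libraries of highest stroma score KO called 563 genes in NK cells.

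Leaving out 1 library at a time, KO called 31 to 428 genes in NK cells, 4 to 17 in ILC1, 40 to 183 in CCR6-negative ILC3 and 25 to 75 in CCR6-positive ILC3. The differences from CCR6-positive ILC3 had 2 to 21 genes for NK cells and 0 to 1 for ILC1. In WT the counts were 301 to 396 for the ILC3 subsets, 551 to 953 for ILC1 against NK cells and 206 to 341 for CCR6-negative ILC3 against ILC1. In the wild-type table they were 1653 to 2790 for SI NK cells, 534 to 1502 for ILC1, 864 to 2323 for ILC2, 946 to 1802 for CCR6-negative and 1935 to 3521 for CCR6-positive ILC3, 513 to 735 for the ILC3 subsets and 388 to 623 for ILC1 against NK cells. LI against SI had 493 to 1229, in ILC2 148 to 205, and infection 21 to 315.

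With an estimated correlation 43 of 126 list calls held. Genes called in the same direction in at least 2 subsets numbered 127 at an adjusted p under 0.1 and 26 under 0.01, against 77. The tables correlated at 0.87 over called genes and 0.76 over genes above the median level for the ILC3 subsets, and at 0.74 and 0.67 for ILC1 against NK cells.

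Of 15856 values under alternatives of named genes that were called, 5 changed sign. Of 4868 values of named genes that were not called 179 did, such as Ncr1 in CCR6-positive KO (0.01, and -0.17 without KO 2) and Bcl6 in NK KO (0.21, and -0.04 without WT 1). The 5 follow. In CCR6-positive KO with the stress score as a covariate Dusp1 was at 0.2, Fos at 0.64 and Jun at 0.12; these are members of the score. With title numbers as a block Il2rb was at -0.13 in LI against SI and Bpnt1 at 0.01 after infection.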

Other observations

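Of the tests in this part, those of the stroma score, of calls at equal depth, of the infection batches and of other cell types after infection were chosen only after the results were seen; the splits of libraries were not.

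The first pattern is the set of 99 genes raised in NK cells labelled KO, where stroma markers moved too. Carried-over stromal cells may explain part of it: Adamdec1 dropped from 3.91 to 2.48 (adjusted p = 0.00726) with the stroma score as a covariate, Ogn to 0.85 (adjusted p = 0.138), and 48 of the 99 genes stayed called, with a median size of 1.15 before and 1.03 after. Of the 10 stroma genes 8 were higher in NK WT 1 than in the other 2 WT libraries, where Adamdec1 was also highest (9.87 against 7.7 and 7.88), which leaves this explanation open. Dgat1 (1.54, adjusted p = 0.000452) and Slc16a10 (1.51, adjusted p = 0.0089) stayed called with the covariate. Low depth of the NK WT libraries stays open: with every NK library thinned to 2.56 M reads the median difference of the raised genes was 2.37 against 2.41 on log2(CPM + 1), the test planned beforehand, but thinning leaves the expected CPM as it is and so fixes that outcome; limma kept 95 of the 99 rises (median of 5 draws), yet thinning moved 0 of the 10157 other tested genes by over 1 SE, so this cannot decide, and limma-voom called 2 genes at full depth and 0 in each draw.

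The second pattern is Atp1b2 after infection, a single gene that lay at 11.34 to 14 in 4 of 4 infected libraries and at 4.27 to 9.19 in the 16 others. Within a correction set, 1 library against 1, the lowest difference was 5 and the highest 8.79, against an SD of 1.17 over uninfected libraries. Both pairs also cross the library series: the SL library is the infected one in CCR6-negative ILC3 and the steady-state one in ILC2. Atp1b2 rose in both, which argues against a shift between these sets or series as its source. Other batch differences were not tested. Other cell types carried along were excluded as tested, since their marker lists had a highest median of 0.12 and 0 of 65 members raised. Of 17364 genes 8 lay above every uninfected library in all infected ones, and 1 of them, Atp1b2, by over 1. Infected CCR6-negative ILC3 of both library series held 13.69 and 14, which goes against a single unusual mouse unless both came from it; an unlisted cell type may also give this pattern and was not tested.

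Labels were exchanged between libraries to ask how many genes a grouping without meaning would call. With 3 libraries against 3 the 10 splits are too few to exclude chance: the real split and the highest other gave 16 and 0 genes for KO in ILC1, 151 and 0 in CCR6-negative ILC3, 105 and 0 in CCR6-positive ILC3, and 492 and 0 for the ILC3 subsets, 799 and 1 for ILC1 against NK cells and 382 and 0 for CCR6-negative ILC3 against ILC1 in WT. In the wild-type table the ILC3 subsets gave 945 and 0. In each of these 7 comparisons 1 split, the real one, reached its count.

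NK cells differed: 4 of the 10 splits, the real one among them, gave 159 genes or more, and the highest gave 305. The 3 others gave 269, 296 and 305 genes and each put NK WT 1 and NK KO 1, the libraries with the highest stroma scores (10.28 and 11.29), in 1 arm. Without these 2 libraries 563 genes were called, 141 of the 159 among them. The 2 libraries also share replicate number 1 and correlate at 0.25 after group means are removed, against -0.15 and -0.09 for NK KO 1 with the other WT libraries. Stroma content and the shared number cannot be told apart as the source of this second structure.

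For the test of differing KO effects in NK cells chance is not excluded: the real count was 2, the highest other split gave 333, and 30 of 100 splits gave at least 2. For ILC1 and CCR6-negative ILC3 limma called 0 genes (288 and 128 at an unadjusted p under 0.05, and 0 by limma-voom), which every split reaches, so the splits decide nothing there; the highest others gave 58 and 43. The 333 genes come from a split that exchanges all NK labels and so adds the 2 KO effects.

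For CCR6-negative ILC3 against the other SI subsets 1 of 100 splits, the real one, reached 1748 genes, and the highest other gave 808. CCR6-positive ILC3 gave 3340 genes, with 808 in the highest other and 1 of 100 splits as large. These splits mix the sorted subsets, so they show that the subsets differ and do not test the size of these counts. For LI against SI 1 of 96 splits, the real one, reached 1182 genes, and the highest other gave 686. This excludes chance only if the libraries are independent. LI ILC2 1 and the steady-state LI library of each ILC3 subset share title number 1, library series and the first correction set. The splits thus cannot exclude a difference that these libraries share. They also exchange libraries across correction sets, and the count was 580 with the sets as batch term and 4 with the title numbers as a block. For infection the 18 splits are too few, with 56 genes in the real split and 442 in the highest other; 2 splits, the real one included, reached 56. The split with 442 genes sets the steady-state replicate 1 libraries of all 3 subsets with CCR6-negative infected 2, and so nearly follows the correction sets. With those sets as batch term 3 genes were called.

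The 2 libraries SI NK 4 and SI ILC1 4 come from male mice by their reads: Xist, the RNA of the inactive X chromosome, had values of 5.07 and 4.69, against 15.07 to 17.58 in the other 18 libraries. In the Bcl6 table all libraries had the Y-linked gene Ddx3y at 11.46 to 12.84. Xist there lay from the floor of 7.28 to 9.38 in NK WT 1, so some of these libraries hold Xist reads. In the wild-type table, sex is therefore shared by NK 4 and ILC1 4 and set apart from the rest. The genes of these 2 subsets were thus also tested without these libraries.

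Reads over the deleted exons, the number of mice per library and the cohort of each genotype would settle most of what is open here. After infection, the 3 genes that stayed called with the correction sets as batch term were Atp1b2 (6.38), Abca1 (3.03) and Slc25a37 (1.75); with the title numbers as a block 0 were called, these 3 included (6.68, 3.15 and 1.88).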
